A study of Rattus norvegicus with 1008 samples.

How the data were processed

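Per the labels, RNA from 12 tissues of Sprague Dawley rats was measured by TempO-Seq with the rat S1500+ panel, version 1.2, after 5 days of 3:3 FTCA or corn oil by gavage. The deposited tables hold counts, whole numbers per probe and library, 1 table for each of 21 sets of 1 tissue and 1 sex, with no normalization. HISAT2 is named by the authors without its version or role, and the counter, the genome build and any filter are not stated. Each table line carries the whole vector of probe IDs, and line i was matched to the i-th ID, an order checked to be the same in all 21 tables. The match of lines to IDs was not checked against another source, and each named gene rests on it. The panel targets 2603 genes, 35 of them with more than 1 probe, and 2395 target symbols matched a RefSeq symbol and 100 more a synonym. No genome was used here, and no coordinates are given.

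Groups were taken from the labels: 8 vehicle libraries and 5 at each of 8 doses per set, 1008 libraries in all. Libraries with a labelled quality issue (7) were left out, as was library r25.2 of male heart at 1 mg/kg/day, which repeats an animal number, leaving 1000 libraries. Male heart had no library of animal r48, and so 4 libraries at 100 mg/kg/day. Between 1325 and 2462 probes per set had enough counts to be tested.

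Each set was fitted in edgeR 4.0.16 by the quasi-likelihood method with TMM normalization, filterByExpr (minimum count 10, minimum total 15), robust dispersion and 9 dose groups, and each dose was tested against vehicle. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 within its set and dose. The SE of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM over TMM-scaled library sizes, given as mean ± SD, and log2 CPM used a prior count of 2. The common coefficient of biological variation ran from 0.213 to 0.592 between sets. Sexes were compared in the 9 tissues sampled in both by an interaction term in a joint fit, and shared calls by Fisher's exact test, one-sided, over the probes tested in both sexes, with Benjamini-Hochberg adjustment over the tissues and directions. The sexes of a tissue also differ in the prefix of their titles, which may name a plate. Each sex was set against its own vehicle, but steps along the animal numbers that differ between such plates cannot be told apart from sex.

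Before the data were examined, 37 gene lists were written from general knowledge of pathways and cell types, and the comparisons, the alternatives and the rule for naming genes were fixed. Lists with at least 5 measured probes were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and, as an alternative, an estimated one, adjusted over the lists of a set. The naming rule took, in sets with at least 20 passing probes, the 10 genes up and the 10 down with the largest log2 fold change among probes whose 100 mg/kg/day libraries all lay on the same side of the vehicle mean and whose mean count was at least 10. It added up to 4 members of each list that was called or had 3 passing members, and elsewhere up to 5 probes with the smallest adjusted p. From the genes so named, those in the text, and those searched for outlying libraries and sex differences, were chosen with the values in view, and the searches cover only these. A gene of male brain, found in the search for outlying libraries, is not reported here, and the counts of that search leave it out.

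The lowest responding dose was the lowest at which at least 5 probes passed there and at each higher dose. Benchmark doses were fitted to log2 CPM of probes that varied over the dose groups (adjusted p under 0.05 in the F test over all doses) by at least 1.5-fold. The 4 curve families were linear, power, exponential and Hill, with shapes on fixed grids and the best taken by AIC. The benchmark response was 1 residual SD, and intervals are the 5th to 95th percentiles of 100 resamples of animals within doses.

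Alternatives fixed in advance were DESeq2 1.42.0 size factors in the same fit, the DESeq2 Wald test, no filter on low counts, counts summed per gene, vehicle and 100 mg/kg/day libraries alone, the left-out libraries kept, and each vehicle and top dose library left out in turn. For benchmark doses they were responses of 0.5 and 1.5 SD, the Hill curve alone, a fold minimum of 2 or none, and a prior count of 0.5. Added after seeing the data were the octet (8 consecutive animal numbers) as a random effect in limma-voom or as a term in the curve, limma-voom without the octet, and 100 against 30 mg/kg/day among the libraries of the last octet. For each set, 100 regroupings of the libraries, the real one included, were fitted in the same way. Regroupings break the octets apart, so a count above theirs does not part dose from octet. Figures were drawn with matplotlib 3.10.9.

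The fits were tested on data simulated at the depth and dispersion of 4 sets with 200 changed probes and no octet effect. In male kidney, 28.4% of probes changed 1.5-fold, 71.2% of those changed 2-fold and 98.5% of those changed 4-fold were called. In male liver these shares were 29.9%, 88.1% and 100%, in female liver 37.3%, 83.6% and 100%, and in female thymus 13.4%, 19.7% and 93.9%. With a simulated octet effect of SD 0.5 on the log2 scale, the comparison with vehicle called 420 of 1123 unchanged probes in male liver, the octet as a random effect 8, and the within-octet comparison 6 of 1124. In simulated male kidney data the within-octet comparison called 50.7% of probes changed 2-fold.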

Results

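The short-chain polyfluorinated acid 3:3 FTCA, a fluorotelomer carboxylic acid, was given to male and female Sprague Dawley rats by gavage in corn oil on 5 days. Each sex had 8 vehicle animals and 5 at each of 0.01, 0.1, 0.3, 1, 3, 10, 30 and 100 mg/kg/day. TempO-Seq, a targeted assay that reads short ligated probe pairs, was run with the rat S1500+ panel, which targets 2603 genes. Females gave 11 tissues and males 10, with 9 of them sampled in both sexes, so that 21 sets of 1 tissue and 1 sex held 48 libraries each, 1008 in all. Total counts per library ran from 196116 to 3633687, with the lowest set median, 678657, in male liver and the highest in male brain. The study used these data to derive a transcriptomic point of departure, so each comparison asked in which tissue, and from which dose, transcript levels changed.

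Levels below are mean counts scaled to library size (CPM) ± SD, with n = 8 vehicle and n = 5 dosed libraries. Male heart had n = 4 at 100 mg/kg/day, and ovary and male lung had n = 7 vehicle libraries. Each gene given with values passed the adjusted threshold at 100 mg/kg/day, and all its top dose libraries lay on the same side of the vehicle mean. The exceptions were Acaa2 in male liver with 4 of 5, and Krt4 with 4 of 5 and Sprr1a with 3 of 5 in male thyroid. Several genes also stepped between consecutive blocks of 8 animal numbers, here called octets, which were noticed after the data were seen; the labels give no plate positions. The vehicle animals fill the first octet, and the last octet holds 3 animals at 30 and the 5 at 100 mg/kg/day. Dose and octet therefore cannot be told apart in the comparison with vehicle, and the difference between 100 and 30 mg/kg/day among the last 8 animals, the within-octet value, is given for the main lists and for part of the genes. Both comparisons use the same top dose libraries, on which probes and lists were called. Noise in those libraries pushes both the same way, so shared directions and ratios lean upwards. Values to be had without an effect above 30 mg/kg/day were not computed. Within the octet, lists were tested with the preset correlation alone. Counts there at an unadjusted p under 0.05 are over all probes tested in the set, of which chance gives about 1 in 20.

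At 100 mg/kg/day, probes passed in all 21 sets, with the largest counts in female thymus (998), male kidney (175) and male liver (159), and at least 20 probes in 10 sets. In male kidney, 1 to 4 probes passed at each lower dose, and in male liver the count went from 3 at 3 mg/kg/day to 11 at 10 and 41 at 30 mg/kg/day. Female tissues followed no such order. The count peaked at 10 mg/kg/day in female kidney (364), ovary (277), liver (176), heart (155) and thyroid (113), at 0.01 mg/kg/day in female brain (202), at 1 mg/kg/day in uterus (333) and at 30 mg/kg/day in female adrenal gland (204). Among female tissues, only thymus rose through the top 3 doses, from 384 to 660 to 998 probes.

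**Figure D1:**
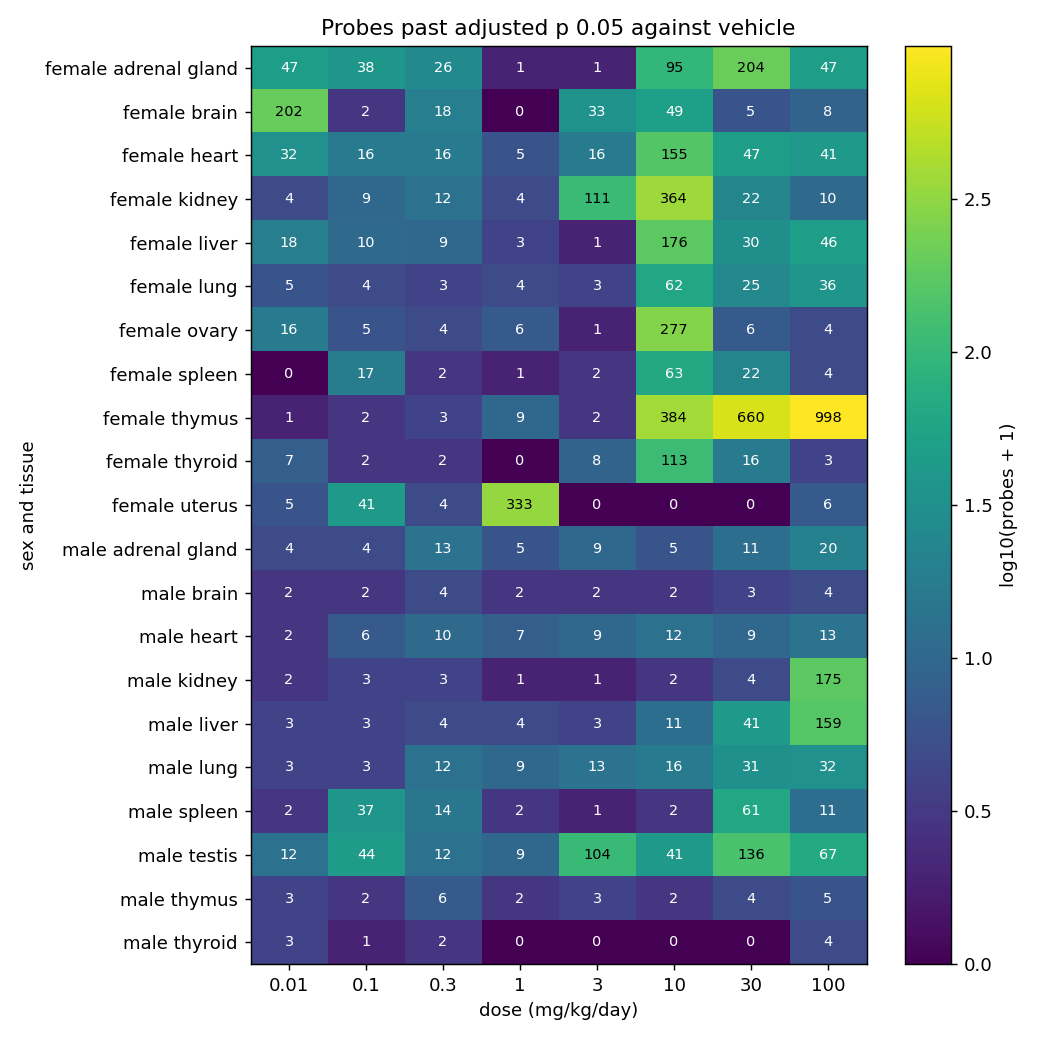
Probes past the adjusted threshold against vehicle, for each of the 21 sets of 1 tissue and 1 sex (vertical axis) and each of the 8 doses in mg/kg/day (horizontal axis), with the count in each cell. Male kidney went from 4 probes at 30 to 175 at 100 mg/kg/day, whereas female kidney held 364 at 10 and 10 at 100 mg/kg/day.

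In male kidney, genes of sterol and fatty acid synthesis rose together at 100 mg/kg/day and genes of the cell division cycle fell. Of 175 probes, 126 rose and 49 fell. Cyp51 (probe Cyp51_8429), a sterol demethylase of cholesterol synthesis, went from 174 ± 19.6 to 419.8 ± 103 CPM (log2 fold change 1.27, SE 0.15, adjusted p = 1.57e-07). Insig1 (probe Insig1_8906), a sterol-regulated membrane protein, went from 1334 ± 182 to 3028 ± 742 CPM (log2 fold change 1.18, SE 0.14, adjusted p = 1.57e-07). Mvd, a decarboxylase of the mevalonate pathway, went from 18.5 ± 2.81 to 38.3 ± 9.13 CPM (log2 fold change 1.05, SE 0.16, adjusted p = 4.66e-05), and Fdft1, the squalene synthase, had a log2 fold change of 0.63 (SE 0.11). The cholesterol synthesis list had 10 of its 18 measured probes higher over all probes and 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.76e-09; adjusted p = 0.0145 with an estimated correlation). Among the last 8 animals the list was also higher at 100 than at 30 mg/kg/day (adjusted p = 0.000207), with within-octet log2 differences of 0.88 for Cyp51 and 0.86 for Mvd, whereas the fatty acid synthesis and cell cycle lists below did not pass there (adjusted p = 0.244 and 0.309).

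The fatty acid synthesis list had 4 of 13 probes higher over all probes and 5 adjusted over the list alone (camera adjusted p = 0.00573; adjusted p = 0.113 with an estimated correlation). Scd, the stearoyl-CoA desaturase, went from 23.6 ± 14.2 to 91.1 ± 16.4 CPM (log2 fold change 1.94, SE 0.32, adjusted p = 0.000110) in male kidney. Fads1, a second desaturase, and Srebf1, a transcription factor of lipid synthesis, had log2 fold changes of 1.27 (SE 0.21) and 1.14 (SE 0.25). Of the 38 cell cycle probes, 8 fell and 1 rose over all probes, and 12 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000190; adjusted p = 0.226 with an estimated correlation). Ccnb2, a mitotic cyclin, went from 81.7 ± 11.1 to 44.7 ± 5.14 CPM (log2 fold change -0.87, SE 0.20, adjusted p = 0.00645), and Cdkn3, a cell cycle phosphatase, had a log2 fold change of -1.11 (SE 0.26). Vegfa, an angiogenic growth factor, rose from 493 ± 27.8 to 773 ± 88.1 CPM (log2 fold change 0.65, SE 0.11, adjusted p = 0.000110), while Ttr, the thyroid hormone carrier transthyretin, fell from 90.6 ± 12.4 to 6.60 ± 3.37 CPM (log2 fold change -3.73, SE 0.39, adjusted p = 4.69e-09).

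Within the last octet, 169 of the 175 male kidney probes moved in the same direction at 100 against 30 mg/kg/day as against vehicle, with a median ratio of the within-octet to the vehicle effect of 0.646. The top dose libraries shared by both comparisons raise both values. None passed alone in that test (edgeR, 251 of 2376 tested at an unadjusted p under 0.05, 77 of them among the 175). That is above the 1 in 20 that chance gives. The count of 175 rested on single libraries: it was 59 without animal r44, 77 without r46, 72 without r47, 82 without r48 and 302 without r45. Leaving out 1 vehicle animal gave 116 without r01, 110 without r02, 110 without r03, 99 without r05, 282 without r07 and 99 without r08. The genes named above in male kidney passed in each of these fits.

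In female kidney, 8 probes rose and 2 fell at 100 mg/kg/day, and the synthesis lists moved as sets. Insig1 went from 738 ± 266 to 1542 ± 560 CPM (log2 fold change 1.06, SE 0.23, adjusted p = 0.00880), and Fdps, the farnesyl diphosphate synthase, from 70.5 ± 13.9 to 112 ± 11.6 CPM (0.67, SE 0.15, adjusted p = 0.0176). Both were chosen after their values were seen, since they were the probes that rose in both kidneys (2 of 8 female and 126 male, 0.436 by chance, Fisher exact one-sided p = 0.0664, adjusted p = 0.171). The cholesterol synthesis list had 2 of 18 probes higher, over all probes and adjusted over the list alone (camera adjusted p = 1.01e-05; adjusted p = 0.0243 with an estimated correlation), and the fatty acid synthesis list 0 and 3 of 13 (camera adjusted p = 0.00449; adjusted p = 0.0243 with an estimated correlation). Insig1 did not differ within the last octet (0.01), and neither list separated 100 from 30 mg/kg/day within the last octet (adjusted p = 0.575 and 0.613). The largest changes were in Amy2a3, an amylase, from 11.3 ± 5.78 to 75.4 ± 17.5 CPM, and Noc2l, from 170.2 ± 47.3 to 18.5 ± 6.65 CPM, with within-octet log2 differences of 0.14 and 0.06. The male minus female log2 fold change was 0.95 for Cyp51 and 1.80 for Mvd in kidney, past the threshold of the interaction test. The Mvd difference is larger than its rise in male kidney. Of the 53 probes past that threshold, 52 had opposite signs in the sexes. The count of 53 ran from 13 without r96 to 121 without r45, was 16 with vehicle and 100 mg/kg/day libraries alone, and none passed within the last octet.

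In male liver, genes of fatty acid oxidation and of drug metabolism rose at 100 mg/kg/day, while fibroblast and matrix genes fell. Of 159 probes, 87 rose and 72 fell. Ehhadh (probe Ehhadh_8534), the bifunctional enzyme of peroxisomal oxidation, went from 96.6 ± 29.2 to 214 ± 38.1 CPM (log2 fold change 1.15, SE 0.18, adjusted p = 2.13e-05). Eci1, an enoyl-CoA isomerase, went from 96.9 ± 28.1 to 212 ± 65.6 CPM (log2 fold change 1.12, SE 0.20, adjusted p = 0.000400), Acot4, an acyl-CoA thioesterase, had 1.40 (SE 0.32), and Acaa2, a mitochondrial thiolase, 0.74 (SE 0.17). The list of PPARα targets of fatty acid oxidation had 8 of 37 probes higher over all probes, and 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0416; adjusted p = 0.554 with an estimated correlation). Cyp3a1, a drug-metabolising cytochrome, went from 1025 ± 361 to 2146 ± 669.7 CPM (log2 fold change 1.07, SE 0.23, adjusted p = 0.00332), and Aldh1a1, a retinal dehydrogenase, had 1.21 (SE 0.28). The list of CAR and PXR targets had 7 of 17 probes higher over all probes and 9 adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.326 with an estimated correlation). Cyp3a probes target near-identical paralogs, so which Cyp3a gene changed is uncertain.

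Sod1, the cytosolic superoxide dismutase, rose from 2402 ± 119 to 3246 ± 325 CPM (log2 fold change 0.43, adjusted p = 0.00514) in male liver. Col3a1, a fibrillar collagen, fell from 964 ± 246 to 37 ± 8.87 CPM (log2 fold change -4.71, SE 0.31, adjusted p = 3.22e-16), and the fibroblast and matrix list had 3 of 10 probes lower (camera adjusted p = 0.00131; adjusted p = 0.199 with an estimated correlation), 3 lower and 1 higher adjusted over the list alone. Spp1, osteopontin, had -0.77 (SE 0.18), Hsd3b, a steroid dehydrogenase, -0.65 (SE 0.13), and Star, the mitochondrial cholesterol carrier, -0.95 (SE 0.22). The steroidogenesis list had 2 of 9 probes lower over all probes, and 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0416; adjusted p = 0.244 with an estimated correlation). Cell cycle had 1 of 10 probes higher, over all probes and adjusted over the list alone (camera adjusted p = 0.0416; adjusted p = 0.508 with an estimated correlation), and was higher within the last octet as well (adjusted p = 9.69e-08). The other lists of male liver did not pass there: PPARα targets (adjusted p = 0.222), CAR and PXR targets (0.259), fibroblast and matrix (0.334) and steroidogenesis, which was higher there (0.871). F10, coagulation factor X, fell from 1440.3 ± 207 to 460.0 ± 97.2 CPM, but its within-octet log2 difference was -0.10 against -1.79 between octets at 30 mg/kg/day. Among the 159 probes, 149 kept their direction within the last octet with a median ratio of 0.339, both raised by the shared top dose libraries. None passed there (edgeR, 72 of 1325 tested at an unadjusted p under 0.05, near the 1 in 20 that chance gives). The count was 59 without animal r44, 103 without r45, 60 without r46 and 103 without vehicle animal r06, and 89 with no filter on low counts.

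**Figure D2:**
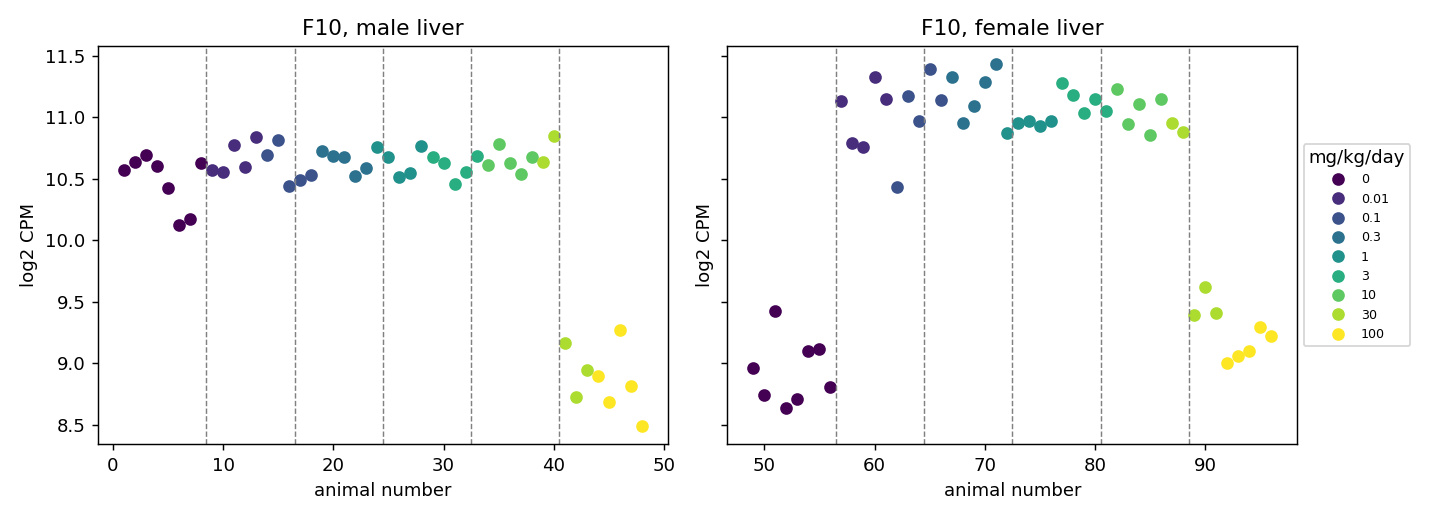
Level of F10 (log2 CPM, vertical axis) in liver by animal number (horizontal axis), 1 point per animal, with dashed lines between octets, in both sexes. At 30 mg/kg/day male F10 differed by -1.79 between the octets, against -0.10 between 100 and 30 mg/kg/day within the last octet.

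In female liver, drug metabolism and oxidative stress genes rose at 100 mg/kg/day, with fatty acid oxidation genes beside them. Of 46 probes, 35 rose and 11 fell. Cyp3a1 (probe Cyp3a1_32809) went from 371 ± 162 to 1556 ± 776 CPM (log2 fold change 2.07, SE 0.41, adjusted p = 0.00142) and Cyp3a2 from 379.8 ± 83.6 to 1279.5 ± 491 CPM (log2 fold change 1.75, SE 0.25, adjusted p = 8.26e-06), with within-octet differences of 1.27 and 1.05. Ephx1, the microsomal epoxide hydrolase, went from 402 ± 113 to 966 ± 255 CPM (log2 fold change 1.26, SE 0.26, adjusted p = 0.00196), with 1.2 within the octet. Akr7a3, an aldehyde reductase, had a log2 fold change of 1.65 (SE 0.29), Akr1b8 1.15 (SE 0.26), Acot2 1.56 (SE 0.33), Vnn1, a pantetheinase, 1.23 (SE 0.22) and Ehhadh 0.99 (SE 0.19). The CAR and PXR list had 9 of 19 probes higher over all probes and 11 adjusted over the list alone (camera adjusted p = 1.31e-15; adjusted p = 5.02e-05 with an estimated correlation). The PPARα list had 9 of 36 (camera adjusted p = 4.48e-06; adjusted p = 0.0297 with an estimated correlation) both ways, and the NRF2 oxidative stress list 4 and 7 of 28 (camera adjusted p = 0.000149; adjusted p = 0.00689 with an estimated correlation). These 3 lists were higher at 100 than at 30 mg/kg/day within the last octet as well (camera with the preset correlation alone, adjusted p = 0.000282, 0.000208 and 0.0175).

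Fgl1, a fibrinogen-like protein secreted by hepatocytes, fell from 6101 ± 1352 to 3384 ± 1081 CPM (log2 fold change -0.85, SE 0.18, adjusted p = 0.00284) in female liver, and Col3a1 from 232 ± 58.3 to 35.4 ± 16.8 CPM. The acute phase list had no single probe past the threshold, over all probes or adjusted over the list alone, and was lower as a set (camera adjusted p = 0.0132; adjusted p = 0.242 with an estimated correlation). Cyp11b3 and Star, genes of steroid synthesis, rose by 1.47 and 1.39 against vehicle but had within-octet differences of -0.46 and -0.22. Within the last octet, 34 of the 46 probes kept their direction with a median ratio of 0.438. No probe passed (edgeR, 74 of 1463 tested at an unadjusted p under 0.05, near the 1 in 20 that chance gives). The count of 46 was 28 with no filter on low counts and 28 with vehicle and 100 mg/kg/day libraries alone. Leaving out 1 library gave 29 without r50, 25 without r53, 29 without r94 and 29 without r95.

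Both livers shared 13 probes that rose, of 33 in females and 85 in males, against 2.15 by chance (Fisher exact one-sided p = 3.05e-08, adjusted p = 5.50e-07). They included Ehhadh, Eci1, Acaa2, Aldh1a1, Akr7a3 and the 3 Cyp3a probes. The 3 that fell in both were Ahsg, Col3a1 and Paqr9 (adjusted p = 0.0527), chosen here after their values were seen. Doses fill the octets in the same order in both sexes. An octet step common to both would give shared calls as well, which the Fisher test does not measure. The effect at 100 mg/kg/day differed between the sexes for 11 liver probes in the interaction test, and Daxx, a nuclear chaperone, was -1.84 in males and 1.30 in females.

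**Figure D3:**
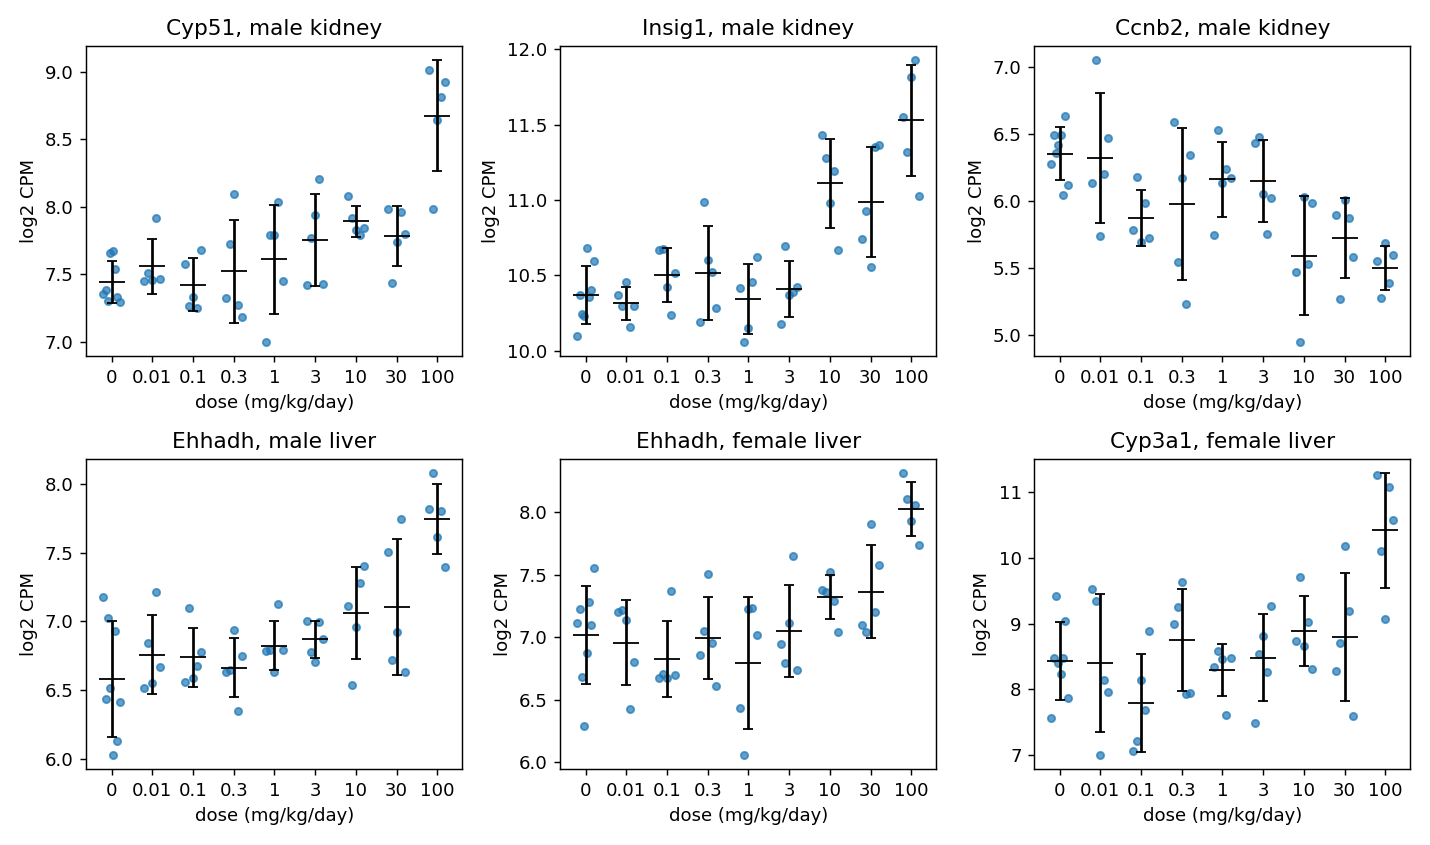
Levels (log2 CPM, vertical axis) by dose (mg/kg/day, horizontal axis) of Cyp51, Insig1 and Ccnb2 in male kidney, Ehhadh in male and female liver and Cyp3a1 in female liver. Each point is 1 animal and the bars give mean ± SD; Cyp51 at 100 mg/kg/day averaged 419.8 CPM against 174 CPM in vehicle.

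In female thymus, adipocyte genes and some replication genes rose at 100 mg/kg/day, and many genes at low levels, among them liver-type cytochromes and transferases, fell. Of 998 probes, 428 rose and 570 fell. Fabp4, the adipocyte fatty acid-binding protein, went from 875 ± 179 to 2919.7 ± 1728 CPM (log2 fold change 1.74, SE 0.26, adjusted p = 5.52e-05), Lpl, the lipoprotein lipase, from 351 ± 44.2 to 629 ± 197 CPM (log2 fold change 0.84, SE 0.22, adjusted p = 0.00299), and Rrm1, a subunit of ribonucleotide reductase, from 966 ± 268 to 1772 ± 224 CPM (log2 fold change 0.87, SE 0.22, adjusted p = 0.00254). Bax, an apoptosis gene, and Prdx1, a peroxiredoxin, had log2 fold changes of 0.75 (SE 0.17) and 0.77 (SE 0.15). Sult2a2, a sulfotransferase, fell from 541 ± 376 to 25.7 ± 13.8 CPM (log2 fold change -4.39, SE 0.87, adjusted p = 0.000364), Cyp3a1 from 220.0 ± 122 to 8.84 ± 3.52 CPM, and Kif11, a mitotic kinesin, from 71.8 ± 51.8 to 4.79 ± 3.15 CPM. The adipocyte list had 9 of 15 probes higher over all probes and 10 adjusted over the list alone (camera adjusted p = 0.0175; adjusted p = 0.368 with an estimated correlation). The CAR and PXR list had 13 of 20 probes lower (camera adjusted p = 0.000612; adjusted p = 0.368 with an estimated correlation) and the sex-biased liver list 15 of 20 (camera adjusted p = 0.000132; adjusted p = 0.368 with an estimated correlation), with as many lower adjusted over the list alone. In each 1 probe rose, or 2 of the sex-biased liver list when adjusted over the list alone. Lists of hepatocyte markers (10 of 19; 0.0483; 0.368), proximal tubule transport (5 of 9; 0.0470; 0.558) and bile acid synthesis (7 of 10; 0.0200; 0.368) were lower beside them, with 10, 6 and 8 lower over the list alone and 2, 1 and 0 probes higher over all probes. Unfolded protein and stress genes were higher (6 of 25, with 2 lower, both ways; 0.0483; 0.368). Of 42 cell cycle probes, 14 rose and 5 fell (camera adjusted p = 0.0562), so the direction of that group was mixed.

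Of the 570 female thymus probes that fell, 70.0% lay below the median level of the set, against 22.2% of those that rose, and with DESeq2 size factors 32.2% of the called probes rose in place of 42.9%. Within the last octet 604 of the 998 kept their direction, with a median ratio of 0.0803. No probe passed (edgeR, 41 of 2453 tested at an unadjusted p under 0.05, fewer than the 1 in 20 that chance gives). No list passed in that comparison (31 lists; the lowest adjusted p was 0.440). The count was 599 without vehicle animal r52, 579 with vehicle and 100 mg/kg/day libraries alone and 51 with the octet as a random effect in limma-voom. The male thymus had 5 probes at 100 mg/kg/day, and the interaction test gave 848 probes that differed between the sexes, 550 without animal r46. Only 298 of the 848 differences had the same direction within the last octet of each sex.

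In female heart, steroid synthesis and drug metabolism genes rose at 100 mg/kg/day. Of 41 probes, 29 rose and 12 fell. Cyp11b3, a steroid hydroxylase, went from 70.3 ± 10.6 to 320.2 ± 46.3 CPM (log2 fold change 2.19, SE 0.19, adjusted p = 3.68e-12), Star from 71.6 ± 13.2 to 259 ± 28.8 CPM (log2 fold change 1.86, SE 0.19, adjusted p = 4.06e-10), and Cyp11a1, which cleaves the cholesterol side chain, from 306 ± 44.3 to 539 ± 92.1 CPM (log2 fold change 0.82, SE 0.12, adjusted p = 9.37e-06). The steroidogenesis list had 5 of 12 probes higher over all probes and 6 adjusted over the list alone (camera adjusted p = 1.85e-13; adjusted p = 2.28e-06 with an estimated correlation), and the CAR and PXR list 5 of 16 higher over all probes and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.23e-06; adjusted p = 0.00213 with an estimated correlation). Cyp2b2, a phenobarbital-inducible cytochrome, had a log2 fold change of 0.92 (SE 0.16), and Apoa2, an apolipoprotein, 1.01 (SE 0.15). Lists of cell-type markers moved in female heart too. Adipocyte markers were lower (0 of 15 probes over all probes, 9 adjusted over the list alone; camera adjusted p = 0.0345; 0.552 with an estimated correlation). So were T and B lymphocyte markers (0 and 1 of 8; 0.0308; 0.444) and fibroblast and matrix markers (1 and 1 of 19; 0.0308; 0.552), and hepatocyte markers were higher (1 and 4 of 22; 0.00599; 0.314). None of the steroid synthesis and drug metabolism genes named above moved within the last octet by as much: Cyp11b3 differed by 0.04, Star by -0.07 and Cyp2b2 by 0.26, and neither the steroidogenesis nor the CAR and PXR list passed there (adjusted p = 0.994 and 0.944). Hbb, a haemoglobin chain, and Alas2, which opens haem synthesis in red cells, fell by 2.23 and 2.52 on the log2 scale, and neither passed without animal r55 or r94. The count was 27 without r94, 22 without r95 and 10 with vehicle and 100 mg/kg/day libraries alone. In male heart, with 13 probes, Apoa2 rose from 31.5 ± 6.49 to 82.5 ± 5.84 CPM, Cyp3a2 from 173 ± 16.7 to 374 ± 42.5 CPM and the secreted protein gene Rup2 from 81.1 ± 17.4 to 181 ± 37 CPM, while Col3a1 fell from 5375 ± 1979 to 371 ± 91.9 CPM.

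In the adrenal gland, plasma protein genes typical of liver and muscle genes fell in females, while in males a muscle gene and liver-type genes rose. Of 47 female probes, 11 rose and 36 fell. Apoa1, an apolipoprotein, went from 522 ± 70.5 to 217 ± 31.5 CPM (log2 fold change -1.27, SE 0.19, adjusted p = 2.05e-05), Ahsg, the plasma protein fetuin-A, from 86.6 ± 13.6 to 36.1 ± 4.72 CPM (log2 fold change -1.26, SE 0.17, adjusted p = 7.35e-06), and C3, complement component C3, from 173 ± 18.9 to 87.5 ± 7.54 CPM (log2 fold change -0.98, SE 0.14, adjusted p = 8.22e-06). Actc1, cardiac actin, had a log2 fold change of -1.15 (SE 0.22). The hepatocyte list had 6 of 21 probes lower over all probes and 9 adjusted over the list alone (camera adjusted p = 2.40e-09; adjusted p = 0.0831 with an estimated correlation), and the muscle list 2 and 6 of 15 (camera adjusted p = 0.000336; adjusted p = 0.105 with an estimated correlation). In males 10 probes rose and 10 fell. Rup2 went from 52.6 ± 8.46 to 151 ± 10.6 CPM (log2 fold change 1.52, SE 0.15, adjusted p = 3.48e-10), Cyp3a2 from 157 ± 49.6 to 335 ± 30.3 CPM (log2 fold change 1.10, SE 0.14, adjusted p = 3.75e-07), and Myl2, a cardiac myosin light chain, had 0.56 (SE 0.11). The muscle list in males had 1 and 4 of 15 probes higher (camera adjusted p = 9.95e-05; adjusted p = 0.0120 with an estimated correlation) and the sex-biased liver list 2 and 4 of 20 (camera adjusted p = 2.09e-05; adjusted p = 0.0382 with an estimated correlation), in each pair the second adjusted over the list alone. Adipocyte markers (0 and 0 of 14; camera adjusted p = 0.0447; 0.839 with an estimated correlation) and fibroblast and matrix markers (0 and 2 of 16; 0.00107; 0.544) were lower in males. Neuronal and glial markers (1 and 3 of 7; 0.0363; 0.197) and the CAR and PXR list (2 of 18 both ways, with 1 lower over the list alone; 0.00121; 0.147) were higher. Within the last octet, 29 of 47 female and 12 of 20 male probes kept their direction. There 121 female probes passed, 0 of them among the 47, and 0 male probes (edgeR, 109 of 2174 tested at an unadjusted p under 0.05). Neither female list passed within the octet, where both were higher (adjusted p = 0.919 and 0.713), and none of the male lists did. Between octets at 30 mg/kg/day 45 of the 47 female probes already moved in the direction of the vehicle comparison, with a median ratio of 0.903 against 0.0751 within the octet. The female count was 92 in DESeq2, and in limma-voom 59 without the octet and 5 with it as a random effect. It was 25 without r92, and the male count 70 without r01, 8 without r44, 7 without r46 and 12 without r48. The male count was 40 in DESeq2. The interaction test gave 111 probes, 51 without r46, 52 without r92 and none within the last octet.

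In lung, 8 probes passed in both sexes, of which 4, Daxx among them, moved in opposite directions and 4 fell in both. Daxx went from 42.3 ± 20.4 to 192 ± 57 CPM in females (log2 fold change 2.18, SE 0.30, adjusted p = 1.22e-05) and from 261 ± 40.8 to 56.1 ± 24.7 CPM in males (log2 fold change -2.21, SE 0.28, adjusted p = 3.59e-07). Col3a1 in males went from 11026 ± 3503 to 592 ± 131 CPM (log2 fold change -4.22, SE 0.47, adjusted p = 1.32e-07). Apoa1 and Ahsg in females had log2 fold changes of -0.93 (SE 0.18) and -0.90 (SE 0.20), and the female hepatocyte list had 4 of 22 probes lower over all probes and 6 adjusted over the list alone (camera adjusted p = 0.00300; adjusted p = 0.589 with an estimated correlation). Star rose by 1.10 in females and fell by 1.22 in males, where the steroidogenesis list had 3 of 14 probes lower both ways (camera adjusted p = 0.0474; adjusted p = 0.476 with an estimated correlation). The male sex-biased liver list had 3 and 8 of 21 probes higher, the second adjusted over the list alone (camera adjusted p = 0.0368; adjusted p = 0.476 with an estimated correlation). In females the same list was lower (0 and 4 of 21), as were cell cycle (0 and 8 of 40) and proximal tubule transport (0 and 3 of 9), each with a camera adjusted p of 0.0165 and of 0.6001 with an estimated correlation. Ahsg, Apoa1, Col3a1 and Ttr fell in both sexes (4 probes against 0.120 by chance, Fisher exact one-sided adjusted p = 3.37e-05). As in liver, an octet step common to both sexes would give shared calls as well. No list named here for lung passed within the last octet (adjusted p of at least 0.2505). Of 36 female and 32 male probes, 27 and 26 kept their direction within the last octet. None passed there (edgeR, 82 of 2462 and 177 of 2334 tested at an unadjusted p under 0.05). The female count was 54 with DESeq2 size factors, of which 24.1% rose in place of 41.7%, and 199 in DESeq2. Without 1 library the female count was 58 (r49), 74 (r50), 21 (r51), 15 (r52), 18 (r53), 62 (r54), 21 (r92), 19 (r93) and 12 (r94). The male count was 7 without r46, 49 without r47 and 15 with the libraries of labelled quality issues kept.

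In testis, Ttr and Tnnc2 fell at 100 mg/kg/day and liver-type genes at low levels rose. Of 67 probes, 53 rose and 14 fell. Ttr went from 548 ± 43.4 to 9.08 ± 1.27 CPM (log2 fold change -5.89, SE 0.33, adjusted p = 1.95e-18), Tnnc2, a troponin of fast muscle, from 14.8 ± 5.20 to 0.479 ± 0.443 CPM (log2 fold change -4.74, SE 0.56, adjusted p = 4.75e-08), and Nr5a1, the nuclear receptor SF-1 of steroid-producing cells, from 179.5 ± 31.5 to 108 ± 17.3 CPM (log2 fold change -0.73, SE 0.14, adjusted p = 0.00188). Cyp3a1 rose from 6.68 ± 3.39 to 28 ± 6.89 CPM and Ttpa, the tocopherol transfer protein, from 8.02 ± 3.05 to 27.5 ± 7.43 CPM. The sex-biased liver list had 6 of 16 probes higher over all probes, and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.78e-05; adjusted p = 0.289 with an estimated correlation). The thyroid hormone response list was lower as a set (1 of 7 probes both ways; camera adjusted p = 1.91e-05; adjusted p = 0.000371 with an estimated correlation), and its lower member was Ttr. Fibroblast and matrix markers (2 and 3 of 18; camera adjusted p = 0.00371; 0.487 with an estimated correlation) and macrophage and neutrophil markers (0 and 0 of 13; 0.0312; 0.476) were lower too. Within the last octet 31 of 67 probes kept their direction and none passed (edgeR, 75 of 2174 tested at an unadjusted p under 0.05). Ttr differed by 0.19 there. The count was 43 without r03, 35 without r05, 44 without r07, 14 without r45, 105 without r46 and 27 without r48. It was 106 in DESeq2, and in limma-voom 57 without the octet and 15 with it as a random effect.

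Fewer than 20 probes passed in the other sets. In female brain, Hmgb2, a chromatin protein, went from 279 ± 103 to 851 ± 82.6 CPM and Amy2a3 from 10.0 ± 4.09 to 63.7 ± 7.29 CPM. In male brain, Pck1, the gluconeogenic carboxykinase, rose from 35.1 ± 4.81 to 65.3 ± 7.75 CPM. App, the amyloid precursor, rose from 86.9 ± 32.5 to 365 ± 138 CPM in female spleen and from 373 ± 144 to 1465 ± 212 CPM in female thyroid. In male spleen Pck1 rose from 36.5 ± 4.45 to 70.3 ± 11.6 CPM and Ttr fell from 65.5 ± 9.46 to 6.91 ± 4.26 CPM, and the cell cycle list had 0 of 41 probes past the threshold over all probes and 20 lower adjusted over the list alone (camera adjusted p = 5.77e-20; adjusted p = 0.108 with an estimated correlation). In ovary Ttr rose from 35.3 ± 8.31 to 239 ± 28.4 CPM and Daxx from 62.9 ± 15.1 to 165 ± 44.5 CPM. In male thymus Ttr fell from 531 ± 131 to 9.44 ± 5.73 CPM and Tnnc2 from 544 ± 236 to 50.9 ± 24.7 CPM. The probes of uterus and of male thyroid passed narrowly: 0 to 2 and 0 to 8 passed when 1 library was left out, and the male thyroid Krt4 change of 4.96 ± 8.06 to 373 ± 788 CPM ended without animal r48 (log2 fold change 2.04, past the threshold no more).

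Daxx and Ttr each passed in 12 of the 21 sets. Daxx was higher in 6 female sets and lower in 6 male sets, and in none of them did 100 differ from 30 mg/kg/day in that direction within the last octet at an unadjusted p under 0.05. Ttr rose in 3 and fell in 2 female sets and fell in 7 male sets, with such a difference in 1. In limma-voom with the octet as a random effect 71 probes passed in male liver, 14 in female liver, 17 in female heart, 21 in female lung and 7 in male lung, against 146, 41, 38, 29 and 21 without the octet. Between octets at 30 mg/kg/day, 83 of 175 probes in male kidney and 50 of 159 in male liver moved in the direction of the vehicle comparison. So did 32 of 46 in female liver, 30 of 41 in female heart, 19 of 36 in female lung and 788 of 998 in female thymus. The counts were 12 of 20 in male adrenal gland, 19 of 32 in male lung, 50 of 67 in testis and 45 of 47 in female adrenal gland. Col3a1 fell in 7 sets, Cyp11b3 and App each rose in 5 female sets, and Star passed in 6.

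**Figure D4:**
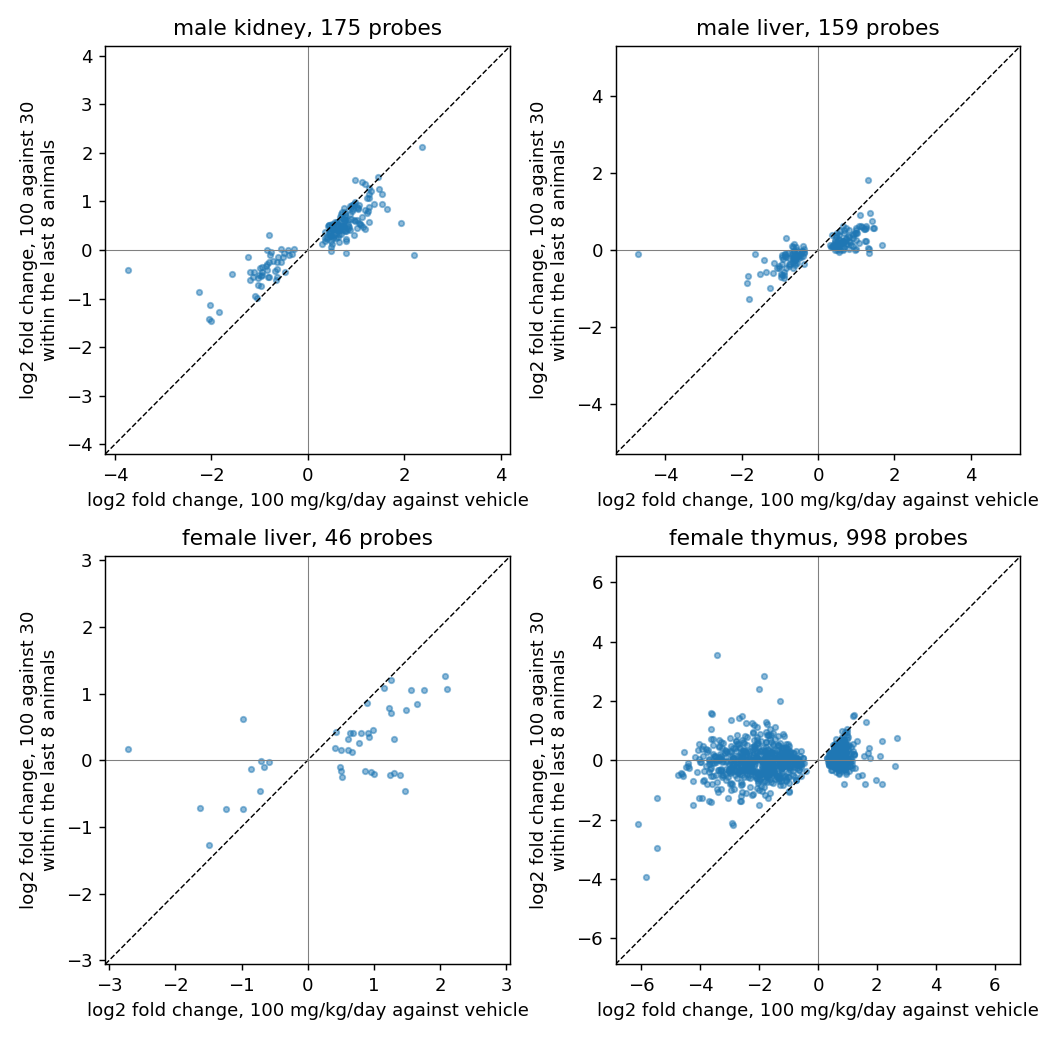
Log2 fold change at 100 mg/kg/day against vehicle (horizontal axis) and log2 difference of 100 against 30 mg/kg/day among the last 8 animals (vertical axis), 1 point per probe past the threshold, in 4 sets. The median ratio of the vertical to the horizontal value was 0.646 in male kidney, 0.339 in male liver, 0.438 in female liver and 0.0803 in female thymus. Both axes use the same 100 mg/kg/day libraries.

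The lowest dose from which at least 5 probes passed at that and each higher dose was 100 mg/kg/day in male kidney, 10 in male and female liver, female thymus, adrenal gland and lung, and 3 in female kidney. It was 0.3 mg/kg/day in male adrenal gland and lung and 0.01 in female heart and testis. When at least 20 probes were asked for, these 4 values were 100, 30, 10 and 3 mg/kg/day, and that of male adrenal gland was 30 with no filter on low counts and 0.01 in DESeq2. The value for male kidney fell to 30 mg/kg/day in DESeq2 and without any 1 of 12 animals, among them r05, r47 and r48. That for male liver was 0.3 without r05, 3 without r06, 30 without r36 and 100 without r40. In DESeq2 it was 0.3 in male liver, 0.01 in female liver and 1 in female thymus. The value for female kidney lay between 0.01 and 0.3 mg/kg/day without any 1 of 38 animals, and at 0.01 in DESeq2.

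Benchmark doses, the dose at which a fitted curve departs by 1 residual SD, were computed for the gene lists with at least 3 responding probes. In male kidney the median was 5.36 mg/kg/day for fatty acid synthesis (resampling interval 2.60 to 12.0) from Fads1, Scd and Srebf1, and 15.6 (5.13 to 21.3) for cholesterol synthesis from Cyp51, Fdft1, Insig1 and Mvd. In male liver the PPARα list, from Acaa2, Eci1 and Ehhadh, had 10.7 mg/kg/day (5.91 to 30.3). Female liver gave 33 (14.2 to 50.3) for CAR and PXR targets, 38.8 (29.1 to 69.1) for PPARα targets and 53.9 (24.5 to 67.7) for NRF2 targets. Its other lists had 6.63 (2.85 to 17.4) for hepatocyte markers, 25.3 (3.67 to 62.9) for steroidogenesis and 29.5 (6.82 to 42.3) for sex-biased liver. The lowest medians of any list were 0.0209 (0.0102 to 71.7) for fibroblast and matrix markers in female heart and 0.0389 (0.00644 to 0.109) for steroidogenesis in male lung, from 3 probes each. The male lung list had no median with the octet term or a fold minimum of 2, nor the female heart list at a response of 1.5 SD. In female kidney cholesterol synthesis had 0.202 mg/kg/day (0.0736 to 3.18) from 3 probes, Fdps, Idi1 and Insig1. With the octet as a term in the curve the male kidney cholesterol median was 53 mg/kg/day, and the female kidney list and the male liver PPARα list kept fewer than 3 probes. Over all responding probes the median was 4.47 mg/kg/day in male kidney (35 probes), 3.27 in male liver (20), 5.40 in female liver (84), 2.22 in female kidney (107) and 10.9 in female thymus (691). With the octet term these medians were 6.77, 19.6, 1.83, 8.57 and 5.11 mg/kg/day, in the same order. The study's own summary used classes of the Gene Ontology, which were not at hand, so these medians are not its point of departure.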

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

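The tests of octets, of equal depth and of 100 against 30 mg/kg/day within the last octet in this part were chosen only after the results were seen; the search for outlying libraries and the test of the sexes were planned. At 100 mg/kg/day the effect differed between the sexes in 78 cases of a named gene in a tissue, 56 genes in all, by the interaction term of the joint fit. Values are the male minus the female log2 fold change. Of the 78, 42 had the same direction in 100 against 30 mg/kg/day within the last octet of each sex, near the 50% of chance. So an octet effect is not excluded for them.

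In kidney the male effect lay above the female one for Cyp51 (0.95), Mvd (1.80), Aldoa (0.79), Gpx1 (3.25), Phgdh (2.5) and Noc2l (3.52). It lay below for Ttr (-4.79), Amy2a3 (-3.08), Fstl1 (-2.28) and Hmgb2 (-1.86). In liver every named difference was negative: Daxx (-3.13), Star (-2.34) and Col3a1 (-1.99), F10 (-1.84), Cyp11b3 (-1.81), Spp1 (-0.99) and Hsd3b (-0.86). At 30 mg/kg/day female F10 (log2 CPM) was at least 10.88 in the fifth octet and at most 9.62 in the last. In heart the difference was negative for Star (-2.31), Cyp11b3 (-2.24), Hsd3b (-1.15), Cyp11a1 (-0.99), Daxx (-3.94) and Spp1 (-1.72) and positive for Rup2 (1.04). In the adrenal gland the male effect was the higher one for Csrp3 (1.74), Actc1 (1.64), Ckm (1.19) and Myl2 (1.16), Apoa2 (1.42), Apoa1 (1.26), Ahsg (0.89) and C3 (0.86). So did Rup2 (2.04), Cyp3a2 (1.55), Cyp2b1 (1.07) and Gria2 (1.07), while Daxx (-3.68), Psmb10 (-1.43), Atf4 (-1.28), Acadm (-1.23) and Nr5a1 (-1.16) lay below.

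Lung differences were positive for Cyp2c24 (9.16), Ucp1 (5.90), Ust4r (3.86) and Ero1lb (3.32), Cyp3a2 (2.38) and Rup2 (1.34). They were negative for Daxx (-4.38), Star (-2.31), Cyp11b3 (-1.61) and Serpinh1 (-1.38) and for Hyou1 (-1.08), Hsd3b (-1.01) and Cyp11a1 (-0.96). In thymus the male effect was above the female one for Cyp3a1 (5.08), Otc (5.00), Ugt2b1 (4.88), Sult2a2 (4.75) and Ust4r (4.43), for Kif11 (4.28), Cyp19a1 (4.08), Cyp2c11 (3.73) and Esr2 (3.72) and for Ccnb1 (3.21) and Pde1b (1.17). The negative thymus differences were Ttr (-8.39), Tnnc2 (-5.49), Daxx (-3.60) and Spp1 (-1.29), Prdx1 (-1.15), Ect2 (-1.10), Bax (-1.08) and Rrm1 (-1.04). In spleen they were Ttr (-5.05) and App (-2.11), with Noc2l (2.77) positive, in thyroid App (-2.35) and in brain Hmgb2 (-1.21).

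A single library lay apart from the rest of its group in 26 of the 430 groups of named genes reported here, against 21.5 that chance gives at 1 in 20 groups. Values are the gap to the nearest library as a share of the range of the group. In male kidney, animal r45 was lowest at 100 mg/kg/day for Acaca (0.991), Vldlr (0.743), Hsp90b1 (0.845) and Idh2 (0.796), and without it 302 probes passed in place of 175. In male liver vehicle animal r01 was lowest for Fgg (0.571) and Ppp1r3b (0.558). Male thyroid animal r48 was highest for Sprr1a (0.864) and LOC100912222 (0.732). In female thymus r52 was lowest for Ect2 (0.637) and r56 highest for Daxx (0.604) among vehicle animals, and r94 lowest at 100 mg/kg/day for Prdx1 (0.712). Female heart had r93 highest for Spp1 (0.838) and r95 for Apoa2 (0.746). Vehicle animals r56 and r50 of female adrenal gland were lowest for C3 (0.583) and Sqstm1 (0.555). Male adrenal vehicle animals r08 and r01 were highest for Cyp3a2 (0.574) and lowest for Daxx (0.805). At 100 mg/kg/day r48 was highest there for Daxx (0.833) and r45 for Crkl (0.759). In lung, female r96 was highest for Cyp2c24 (1.00), male r47 lowest for Col3a1 (0.911) and male r48 highest for Rup2 (0.764). Testis r07 was lowest for Daxx (0.577) and uterus r94 highest for Arhgap9 (0.721). In female thyroid vehicle r50 and r52 were highest for App (0.536) and Hmgb2 (0.721).

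Levels stepped between octets of animals that received the same dose. In 31 of 83 sets and doses the split by octet separated the libraries more than any other split of the same sizes, against 12.45 by chance. Within 30 mg/kg/day 1257 probes in 17 sets differed between octets, 658 of them outside female adrenal gland. For these probes library depth was argued against, since 73% as many differed after thinning to equal depth. Handling of libraries in octets was not tested apart from the steps themselves. Title prefixes may name a plate per tissue and sex, but no day or position is given. What octets shared therefore stays open, and no biological explanation was tested.

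More probes passed at 10 than at 30 and at 100 mg/kg/day in 8 female tissues, 1259 in all, and the 10 mg/kg/day animals fill most of the fifth octet. The exceptions were uterus, thymus and adrenal gland. Against the 3 animals of other doses in that octet, the effect was 0.197 of that against vehicle (median over the 8 tissues, 0.00758 to 0.283). There 0 probes passed (edgeR, 1374 at an unadjusted p under 0.05). The 3 animals had 3 (r81) and 30 mg/kg/day (r87 and r88), so an effect of dose that lasts to 30 mg/kg/day would give a low ratio too. Dose as the cause was therefore not decided by this comparison. Library depth, low in this octet, was argued against as the whole cause, with 78.3% as many probes after thinning. Handling in octets is a candidate cause: 79.9% of the probes had the 3 mg/kg/day animal r81 of this octet on the side of the 10 mg/kg/day effect, and 87.6% had r87 and r88 there. These are 3 animals sampled in each tissue, and an effect of dose stays open.

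In female thymus 998 probes passed at 100 mg/kg/day. A rise of dose above 30 mg/kg/day as the whole cause was argued against by a within-octet effect that was 0.0803 of the effect against vehicle (median over the probes). Library depth was argued against by 722 probes after thinning, 72.3% as many, of which 692 were among the 998. Handling in octets could not be decided. The 30 mg/kg/day animals r89 to r91 of the last octet lay on the side of the effect from r87 and r88 for 79% of the probes, but only 10 probes differed between these octets (4 after thinning), and 3 of the 10 splits of the 5 animals separated them as much as the octet did. An effect of dose already full at 30 mg/kg/day stays open and untested. The sexes differed in 848 thymus probes, 298 of them in the same direction within the last octet, so the source of that difference stays open too.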

How the results depend on the processing

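The comparison of 100 with 30 mg/kg/day within the last octet and both uses of the octet in a model, with limma-voom without the octet, were chosen only after the data were seen; the other alternatives were planned. Genes named by the rule kept their direction and their side of the threshold in 399 of 403 cases in DESeq2, 397 of 410 with DESeq2 size factors, 384 of 410 with no filter on low counts and 401 of 410 with counts summed per gene. With the libraries of labelled quality issues kept, 25 of 39 did, with male heart library r25.2 kept 5 of 5, with vehicle and 100 mg/kg/day libraries alone 304 of 399, and when 1 library was left out 4451 of 5299. Only the Aldoa probe Aldoa_8030 in female thymus reversed, to a log2 fold change of 0.30 with counts summed per gene, where its counts are added to those of 2 Aldoa probes at far higher levels. Values in parentheses below are those with the settings used for the report; for each, the cause was not tested unless it is given. No paired analysis was possible, since each tissue was sampled once per animal, at 1 dose.

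Within the last octet, with 5 libraries against 3 in place of 8, 0 probes passed in 18 of the 21 sets in edgeR, at between 27 and 365 with an unadjusted p under 0.05, while the count went to 121 in female adrenal gland (47) and 4 in female heart (41). The number of lists there was 0 in female brain (3), female kidney (6), female ovary (4), female thymus (7), male adrenal gland (6), male heart (3) and male testis (4). It went to 3 in female heart (9), 7 in female spleen (2), 3 in female uterus (1), 3 in male brain (5), 1 in male kidney (3), 2 in male liver (5), 1 in male thymus (3) and 2 in male thyroid (1). No sex difference passed there in adrenal gland (111), brain (4), heart (23), kidney (53), liver (11), lung (213), spleen (4) and thymus (848). With the octet as a random effect in limma-voom, probe counts were 5 in female adrenal gland (47), 1 in female brain (8), 17 in female heart (41), 14 in female liver (46) and 21 in female lung (36). Counts with that model were also 0 in female ovary (4), 51 in female thymus (998), 0 in female uterus (6), 8 in male heart (13) and 71 in male liver (159). It further gave 7 in male lung (32), 1 in male spleen (11), 15 in male testis (67) and 0 in male thyroid (4). The correlation within octets was estimated below 0 in female spleen and thyroid and in male adrenal gland, brain, kidney (-0.0483) and thyroid, and there the fit is limma-voom alone. Without the octet limma-voom gave 0 probes in female uterus (6) and male thyroid (4) and 21 in male lung (32), so there the tool accounts for all or part of the move; its other counts lay within 1.5 times of those in edgeR.

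With the correlation between genes estimated, no list passed in female adrenal gland (2), female brain (3), female lung (4), female ovary (4), female spleen (2), female thymus (7) and female thyroid (3). The same held for female uterus (1), male heart (3), male liver (5), male lung (2), male spleen (2), male thymus (3) and male thyroid (1). The count of lists was 2 in female heart (9), 2 in female kidney (6), 2 in male adrenal gland (6), 1 in male brain (5), 1 in male kidney (3) and 1 in male testis (4). With vehicle and 100 mg/kg/day libraries alone, which estimates dispersion from fewer libraries, the probe count was 93 in female adrenal gland (47), 10 in female heart (41), 3 in female kidney (10), 28 in female liver (46) and 22 in female lung (36). It was 2 in female spleen (4), 579 in female thymus (998), 0 in female uterus (6), 13 in male adrenal gland (20) and 0 in male brain (4). In the remaining sets it was 15 in male lung (32), 3 in male thymus (5) and 0 in male thyroid (4). Sex differences then numbered 0 in brain (4), 13 in heart (23), 16 in kidney (53) and 1 in thyroid (2).

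In DESeq2 the probe count was 92 in female adrenal gland (47), 38 in female brain (8), 18 in female kidney (10), 199 in female lung (36) and 9 in female ovary (4). That tool gave 14 in female spleen (4), 6 in female thyroid (3), 40 in male adrenal gland (20), 15 in male brain (4) and 55 in male lung (32). It also gave 42 in male spleen (11), 106 in male testis (67) and 8 in male thyroid (4). The lowest dose in DESeq2 was 0.01 in female kidney (3), 0.01 in female liver (10), 1 in female thymus (10), 0.01 in male adrenal gland (0.3), 30 in male kidney (100) and 0.3 in male liver (10). When at least 20 probes were asked for, the lowest dose was 10 in female heart (0.01), 100 in male adrenal gland (0.3), 30 in male liver (10), 30 in male lung (0.3) and 3 in male testis (0.01). With no filter on low counts the probe count was 28 in female liver (46), 0 in female uterus (6) and 89 in male liver (159). The number of lists was then 4 in female thymus (7), 0 in male lung (2) and 7 in male testis (4). Without that filter the lowest dose was 0.1 in female kidney (3), 30 in male adrenal gland (0.3) and 30 in male liver (10). Sex differences without the filter numbered 7 in liver (11). With DESeq2 size factors the lists numbered 1 in female spleen (2) and 4 in female thymus (7). Probes with these factors numbered 0 in female uterus (6). With the libraries of labelled quality issues kept, probes numbered 83 in female ovary (4), 1 in female thyroid (3) and 15 in male lung (32). Sex differences were then 0 in brain (4).

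Median benchmark doses in mg/kg/day were, at a response of 1.5 SD, 54.7 for CAR and PXR drug metabolism in female liver (33), 72.9 for NRF2 oxidative stress in female liver (53.9) and 25.5 for cholesterol synthesis in male kidney (15.6). At 0.5 SD they were 19.2 for PPARα fatty acid oxidation in female liver (38.8), 2.45 for fatty acid synthesis in male kidney (5.36) and 4.89 for PPARα fatty acid oxidation in male liver (10.7). A fold minimum of 2 gave 68.5 for NRF2 oxidative stress in female liver (53.9) and 25.6 for cholesterol synthesis in male kidney (15.6). With the octet as a term in the curve the medians were 8.73 for unfolded protein and integrated stress in female kidney (3.29), 69.1 for sex-biased liver in female liver (29.5) and 53 for cholesterol synthesis in male kidney (15.6). The female kidney cholesterol list had too few probes for a median with a response of 1.5 SD, a fold minimum of 2 or the octet term. The male liver PPARα list had too few with a fold minimum of 2 or the octet term, and the female liver PPARα list with a fold minimum of 2. Over all responding probes, the medians with the octet term are given above.

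When each library was left out in turn, probe counts ran from 25 to 67 in female adrenal gland, 5 to 24 in female brain, 22 to 61 in female heart, 25 to 44 in female liver, 12 to 74 in female lung and 3 to 7 in female ovary. They ran from 599 to 1078 in female thymus, 1 to 3 in female thyroid, 0 to 2 in female uterus, 7 to 70 in male adrenal gland, 4 to 20 in male brain and 7 to 12 in male heart. The others ran from 59 to 302 in male kidney, 59 to 183 in male liver, 7 to 49 in male lung, 3 to 31 in male spleen, 14 to 105 in male testis and 3 to 5 in male thymus. The last ran from 0 to 8 in male thyroid. Lists ranged from 2 to 5 in female adrenal gland, 0 to 3 in female brain, 4 to 7 in female liver, 1 to 3 in female spleen, 4 to 6 in female thymus and 2 to 6 in female thyroid. In the same fits lists ranged from 0 to 2 in female uterus, 3 to 8 in male brain, 1 to 4 in male heart, 3 to 7 in male kidney, 2 to 5 in male liver and 0 to 3 in male lung. In male thyroid lists ranged from 0 to 4. The lowest dose ranged, in mg/kg/day, from 0.01 to 3 in female kidney, 30 to 100 in male kidney and 0.3 to 100 in male liver. Sex differences ranged from 51 to 110 in adrenal gland, 0 to 4 in brain, 14 to 21 in heart, 13 to 121 in kidney, 5 to 23 in liver and 115 to 220 in lung. They ranged also from 550 to 887 in thymus and 1 to 7 in thyroid.

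Single libraries that moved a count more than 1.5 times were found, outside the 10 sets with at least 20 probes, in female brain (24 without r52, 5 without r94), female ovary (7 without r53), female thyroid (1 without r49, r50, r51, r53, r54, r55, r56, r93, r95 or r96) and female uterus (0 without r49, r50, r51, r52, r53, r54, r55, r92, r93, r94, r95 or r96, 2 without r56). Others were in male brain (10 without r01 or r45, 7 without r04, 8 without r46, 20 without r47), male heart (7 without r46 or r47), male spleen (6 without r02 or r44, 20 without r03, 7 without r04, 31 without r45, 3 without r46, 5 without r48) and male thymus (3 without r44). Others were in male thyroid (1 without r02, 0 without r03, r05, r06, r07, r08 or r48, 8 without r44, 7 without r46 or r47). For lists they were found in female adrenal gland (4 without r92, 5 without r96), female brain (1 without r92, 0 without r93), female liver (7 without r96) and female spleen (1 without r93, r94 or r96). Lists moved also in female thymus (4 without r94), female thyroid (6 without r93, 5 without r96), female uterus (0 without r93 or r96, 2 without r94 or r95) and male brain (8 without r45, 3 without r47). Lists moved also in male heart (1 without r45 or r46), male kidney (7 without r48), male liver (3 without r44 or r48, 2 without r45) and male lung (1 without r44, r45 or r47, 0 without r48). Lists moved also in male thyroid (4 without r47, 0 without r48). Sex differences moved in adrenal gland (52 without r92, 72 without r44, 51 without r46, 69 without r48), brain (1 without r93, 0 without r44, r46, r48, r94, r95 or r96) and heart (14 without r45 or r92, 15 without r44 or r94). They moved further in kidney (23 without r92, 80 without r93, 20 without r94, 13 without r96, 29 without r44 or r46, 121 without r45, 32 without r47, 18 without r48), liver (6 without r92, 23 without r93, 7 without r44 or r94, 5 without r96) and lung (115 without r46). They moved further in thymus (550 without r46) and thyroid (1 without r48, r93, r94, r95 or r96, 7 without r44, 4 without r45, 5 without r46 or r47).

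In 10 female tissues the libraries of the fifth octet held between 27.3% and 75.3% of the median depth of the other octets. Small changes were often missed in the simulated data, where 28.4% of 1.5-fold changes were called in male kidney and 13.4% in female thymus.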

Other observations

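The tests of haemoglobin genes and of 100 against 30 mg/kg/day were chosen only after the results were seen; the regroupings were planned. Among the lists that changed against vehicle, the cholesterol synthesis genes of male kidney (adjusted p = 0.000207) and the CAR and PXR genes of female liver (adjusted p = 0.000282) changed within the last octet in the direction of their change against vehicle. The PPARα and NRF2 genes of female liver and the cell cycle genes of male liver did so too (adjusted p = 0.000208, 0.0175 and 9.69e-08). So did lymphocyte markers of female heart (0.000324), the sex-biased liver list of female spleen (0.000323) and NRF2 genes of male thyroid (0.00783), all lower. Those 3 and the male liver cell cycle list did not pass against vehicle with the correlation estimated (0.444, 0.706, 0.501 and 0.508). Within the octet, all lists were tested with the preset correlation alone. Against their direction from vehicle, fibroblast markers of female heart rose (0.0441) and cell cycle genes of female thyroid fell (0.0345) within the octet. Neither of them passed against vehicle with the correlation estimated. For the lists that kept their direction, dose above 30 mg/kg/day is a candidate cause beside the octet, which the comparison with vehicle alone cannot part from dose. Within the octet 77 of the 175 male kidney probes had an unadjusted p under 0.05 in the same direction.

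Steroid synthesis genes rose in female heart, where Cyp11b3 and Star differed by 0.04 and -0.07 within the last octet. Both rose in female liver too, where they differed by -0.46 and -0.22 within the octet, against the rise. With the octet as a random effect 17 of the 41 female heart probes passed. No explanation of this rise was tested.

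Red cell genes may mark how much blood a tissue held. In the last octet, over the tissues of each animal, the log2 difference of 100 from 30 mg/kg/day for Hbb was -0.41 in females (exact permutation test, two-sided p = 0.393) and -0.20 in males (exact p = 0.393). For Alas2 it was -0.42 in females (exact p = 0.321) and -0.11 in males (exact p = 0.821). Hba2, whose probes share near-identical paralogs, differed by -0.24 (exact p = 0.607) and -0.08 (exact p = 0.786). With 5 animals against 3 the smallest exact p is 0.0179, and the tests did not decide between dose and octet.

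Each count was compared with 100 regroupings of the same libraries, the real one included, given here as the real count and the highest other. Below, chance is called excluded at a share under 0.05, which was not adjusted over the counts and does not exclude the octet. Over so many counts, some would pass that cutoff by chance alone, so those with 2 to 4 of the splits are weak. At 100 mg/kg/day chance was excluded for female adrenal gland (47 and 28, 1 of the splits) and brain (8 and 1, 1). Female kidney (10 and 17, 3), liver (46 and 3, 1), lung (36 and 1, 1) and ovary (4 and 17, 4) were others. It was excluded also in female spleen (4 and 137, 3 splits), thymus (998 and 767, 1) and thyroid (3 and 43, 2). So it was in female uterus (6 and 2, 1), male adrenal gland (20 and 236, 3) and male heart (13 and 3, 1). Further sets, with 1 split each, were male kidney (175 and 62), liver (159 and 40) and lung (32 and 6). So were male spleen (11 and 3), testis (67 and 3) and thymus (5 and 1), with 1 split each. Chance was not excluded in female heart (41 and 171, 8 splits), male brain (4 and 89, 6) and male thyroid (4 and 22, 25). In male adrenal gland, male brain and female spleen the highest others were many times the real count, and what gave them was not tested.

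For the number of lists, chance was excluded in female kidney (6 and 6, 3 splits) and thymus (7 and 7, 4). So it was in male heart (3 and 4, 3) and testis (4 and 3, 1). For lists it was not excluded in female adrenal gland (2 and 14, 63), brain (3 and 8, 28) and heart (9 and 10, 8). The same held in female liver (4 and 8, 24), lung (4 and 6, 13) and ovary (4 and 9, 22). Nor was it in female spleen (2 and 11, 58), thyroid (3 and 9, 52) and uterus (1 and 10, 99). It was not in male adrenal gland (6 and 9, 16), brain (5 and 7, 12) or kidney (3 and 8, 28). Other sets where lists were as many by chance were male liver (5 and 7, 6) and lung (2 and 9, 48). So were male spleen (2 and 11, 66), thymus (3 and 6, 29) and thyroid (1 and 10, 90).

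Summed over the 7 lower doses, chance was excluded for probes of female adrenal gland (412 and 123, 1 split). So it was in female brain (309 and 329, 2), heart (287 and 92, 1) and kidney (526 and 79, 1). The same held in female liver (247 and 16, 1) and lung (106 and 355, 3). It was also excluded in female ovary (315 and 108, 1 split), thymus (1061 and 781, 1) and thyroid (148 and 34, 1). So it was in female uterus (383 and 506, 2), male brain (17 and 381, 4) and male heart (55 and 26, 1). So it was in male liver (69 and 237, 3 splits), lung (87 and 87, 2) and testis (358 and 61, 1). It was not excluded for the lower doses of female spleen (107 and 1184, 18 splits) and male adrenal gland (51 and 677, 8). Male kidney (16 and 292, 9), spleen (119 and 483, 9), thymus (22 and 1562, 21) and thyroid (6 and 38, 22) were the others. For sex differences, chance was excluded in adrenal gland (111 and 270, 2 splits), brain (4 and 10, 3) and heart (23 and 46, 2). So it was in kidney (53 and 83, 3), liver (11 and 14, 3) and lung (213 and 5, 1). It was excluded as well in spleen (4 and 2, 1 split) and thymus (848 and 929, 2). In thyroid chance was not excluded (2 and 4, 5 of the splits).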
